A study of Homo sapiens with 10 samples.

How the data were processed

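Bulk RNA-seq was measured in 10 libraries of SW480 cells, a line from a human colorectal adenocarcinoma, with 5 libraries of cells positive and 5 of cells negative for ROBO1 after flow sorting. Per the labels' protocols, cells were stored in a phenol reagent until all replicates had been collected, and libraries were made with a stranded kit for polyadenylated RNA. The deposited files hold raw counts of reads per gene, 1 file per library, which the authors did not normalise. Per the submitters' processing notes, STAR 2.6.0c, SAMtools 1.9, FastQC, bcl2fastq and DESeq2 1.24.0 were used with the genome build GRCh38. The counting tool, its strand setting and the gene annotation are not given in the sources used here, so reads of overlapping and antisense genes may not be separated. Entries of the files that name no gene were left out of library sizes and tests. They held the reads with no feature (a mean of 15.8% of all reads listed in ROBO1pos and 14.6% in ROBO1neg), reads aligned to several places (24.6% and 21.2%) and ambiguous reads (between 0.806% and 0.881% per library). Reads on genes made up 58.7% and 63.4%.

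Gene totals per library ran from 23228686 to 29539100. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by edgeR's filterByExpr with default settings, library sizes were scaled by TMM, and a quasi-likelihood model with group as the only term was fitted. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors were derived from the coefficient and its F statistic. Log2 CPM used a prior count of 2. Gene lists, 33 in number, were fixed with their members before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with 5 or more tested genes were tested by camera with a preset correlation of 0.01, with camera's estimated correlation and fry as alternatives. The lists overlap: for example, 20 of the mesenchymal and EMT genes are in another list.

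Named genes were ROBO1; LGR5, ASCL2, SMOC2, OLFM4, PROM1, CD44, ANXA1, CLU and the genes listed in the files as CYR61 and CTGF; the 8 genes with the largest and the 8 with the smallest log2 fold change among called genes of at least 5 CPM in the higher group with no overlap of libraries; up to 4 called members of each list by smallest adjusted p, at most 3 per direction where both occur; and the 2 highest members of the lists of other cell types. ESRRG, LARP4B, ZMYND11, DIP2C and the members of gene families in the closing section were chosen after their values were seen. Some genes that the rule takes are not reported here.

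No within-group pair of libraries was a duplicate: their counts differed by 3.49 to 21.5 times the variance expected from sampling, per degree of freedom. Single values were compared by an exact two-sided permutation test over the 252 assignments. The alternatives were other scalings (RLE, upper quartile, library size only), no filter beyond 1 count, a filter of 5 CPM in 5 libraries, DESeq2 1.42.0, limma-voom, a test against 1.5-fold, the replicate number as a block, each library left out, and 1 surrogate variable from sva 3.50.0. Removal of the median log2 fold change of the 20 nearest genes on each side was added after the data were seen.

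Genes were placed on chromosomes through a RefSeq gene table for GRCh38.p14, by symbol for 13663 tested genes and by an older name for 944, which left 325 without a position. The build's patch release used for the counts is not given in the sources used here. Stretches of shifted genes were sought after the data had been seen, by recursive segmentation of log2 fold changes limited to 1.5 either way, with at least 20 genes per stretch and 200 permutations per step at a threshold of 0.01. The first version of this search, which placed 1 breakpoint at a time, was run on the data before its failure on simulated data was seen. It recovered few planted stretches: 1 of 6 of 80 genes shifted by 0.6 and 3 of 6 of 200 genes shifted by 0.6, though for a shift of 1.0 it recovered 2 of 6 and 6 of 6, with at most 1 other stretch past the threshold of 0.4. It was replaced by a search for 2 breakpoints at a time, which recovered 2 of 6 and 6 of 6, and 6 of 6 for a shift of 1.0 at either size, with up to 3 other stretches past it. Short stretches with small shifts can therefore have been missed, and some stretches found can be false. With 0 stretches planted, 0 passed the threshold, but fold changes had been shuffled over the genome before planting. Simulated neighbours were thus independent, whereas real genes 1 place apart correlated at 0.281. The check does not give the number of false stretches in the data. Predictions for the tests in the closing section were written before this change, except for the test on genes of low and high expression, which was rewritten after the result of a first version, which used genes already chosen for their shift, had been seen. The test of GC content was run again with unchanged bounds. The carry-over test was first computed as a Pearson chi-square and then as the deviance its bound had been set for, and both are given; its bound was later found to leave out the spread of the genes between libraries.

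The gene test was checked on simulated counts for ROBO1pos against ROBO1neg, with 14935 genes tested and 200 changed genes. It recovered 60% of 50 genes changed by 1.25-fold, 88% of 50 changed by 1.5-fold and 100% of 50 changed by 2-fold, and called 13 of 14696 unchanged genes. In the same simulation a planted list of 40 genes raised 1.5-fold was called by camera with either correlation and by fry, and of 30 random lists camera called 0 and fry 1. Simulated genes were independent, so this does not test lists whose members vary together. All of them shared 1 dispersion and few were changed. The simulation therefore does not give the rate of false calls for data in which most genes differ. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used for the chromosome analysis and the figures.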

Results

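Polyadenylated RNA was sequenced from cells of the human colorectal cancer line SW480 that had been sorted by flow cytometry on the surface receptor ROBO1. The labels call the ROBO1-positive population SW480-CBC and the ROBO1-negative population SW480-RSC, and the series title describes them as the cancer stem cell populations of the line. They are named ROBO1pos and ROBO1neg here. Each population had 5 replicates, and 1 comparison follows from the design: ROBO1pos against ROBO1neg. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Between 23228686 and 29539100 reads per library were counted on genes, so that a gene at 1 CPM (counts-per-million) rested on 23.2 to 29.5 counts per library. Gene totals did not differ detectably between the groups (exact two-sided permutation test, p = 0.905), but reads on genes were a smaller share of all reads listed in ROBO1pos (58.7% against 63.4%) and reads with no feature a larger one (15.8% against 14.6%), with p = 0.00794 for each. Of the 26485 genes listed, 5569 had 0 counts in all libraries and 14932 were tested. Expression is given below as CPM, mean ± SD over 5 libraries per group, and log2 fold changes are ROBO1pos minus ROBO1neg.

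ROBO1, the receptor used for sorting, was measured first because it checks the labels and is not an independent finding. It lies on chromosome 3 from 78597239 to 79767998 (GRCh38.p14). ROBO1 reached 430 ± 26.7 CPM in ROBO1pos and 7.25 ± 1.47 CPM in ROBO1neg, a log2 fold change of 5.88 (SE 0.11, edgeR quasi-likelihood adjusted p = 2.6e-14). All libraries labelled ROBO1pos lay above all labelled ROBO1neg, and the exact two-sided permutation p of 0.00794 was the smallest that 5 against 5 libraries can give.

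The populations differed in most of the genes they express. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6214 genes were higher in ROBO1pos and 6036 were higher in ROBO1neg, together 82.0% of the genes tested. Of these, 2021 were at least 2-fold higher in ROBO1pos and 2504 at least 2-fold higher in ROBO1neg, and 268 and 267 respectively were at least 32-fold higher. The libraries of the groups did not overlap for 71.9% of genes, against 0.794% by chance. Libraries of 1 group were close to each other, with Pearson correlations of log2 CPM across genes between 0.989 and 0.996, whereas libraries of different groups correlated between 0.821 and 0.844. The first principal component held 97.6% of the variance of the 500 most variable genes and separated the populations. The biological coefficient of variation was 8.70%, so that small fold changes passed the test. When a difference of over 1.5-fold was required, 2938 genes were higher in ROBO1pos and 3298 in ROBO1neg.

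Among called genes of at least 5 CPM in the higher population and with no overlap of libraries, those with the steepest differences were nearly absent from the other population. Higher in ROBO1pos was NEUROD1, a transcription factor of endocrine and neuronal cells, with 24.2 ± 8.33 CPM against 0.142 ± 0.0668. VAV3, SIT1, ASXL3, LOC100420587, SPANXD and SLC16A7 were also among the 8 largest positive log2 fold changes of these genes, with values from 7.05 for SLC16A7 to 7.16 for VAV3, and NEUROD1 was at 7.37. Higher in ROBO1neg were CCR1, a chemokine receptor, with 8.71 ± 1.97 CPM against 0.0232 ± 0.0346 in ROBO1pos, and ANKRD1, a YAP target, with 508 ± 52.8 against 2.64 ± 1.03. ALPK2, PSG5, SAA2, CDK15, TMEM52B and GNG11 completed the 8 most negative values of these genes, from -8.26 for CCR1 to -7.58 for ANKRD1. CCR1 and CDK15 had 3 counts each over all ROBO1pos libraries, so their ratios of summed counts were 367 (95% exact binomial interval 125 to 1784) and 250.5 (85.4 to 1217), which cover counting error only. Leaving out 1 library moved some folds by over 1.5 times. Without ROBO1pos replicate 3 the log2 fold changes of CCR1, SAA2 and TMEM52B were -9.21, -8.45 and -8.52, without ROBO1pos replicate 2 that of CDK15 was -8.66, and without ROBO1neg replicate 4 that of ASXL3 was 8.37. PSG5 and SAA2 belong to families of near-identical genes and SPANXD to another, so their counts are uncertain. Among genes at 100 CPM or more in the population where they were higher, the lowest level in the other population was 0.863% (ESRRG) in ROBO1neg and 0.425% (PSG5) in ROBO1pos.

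**Figure D1:**
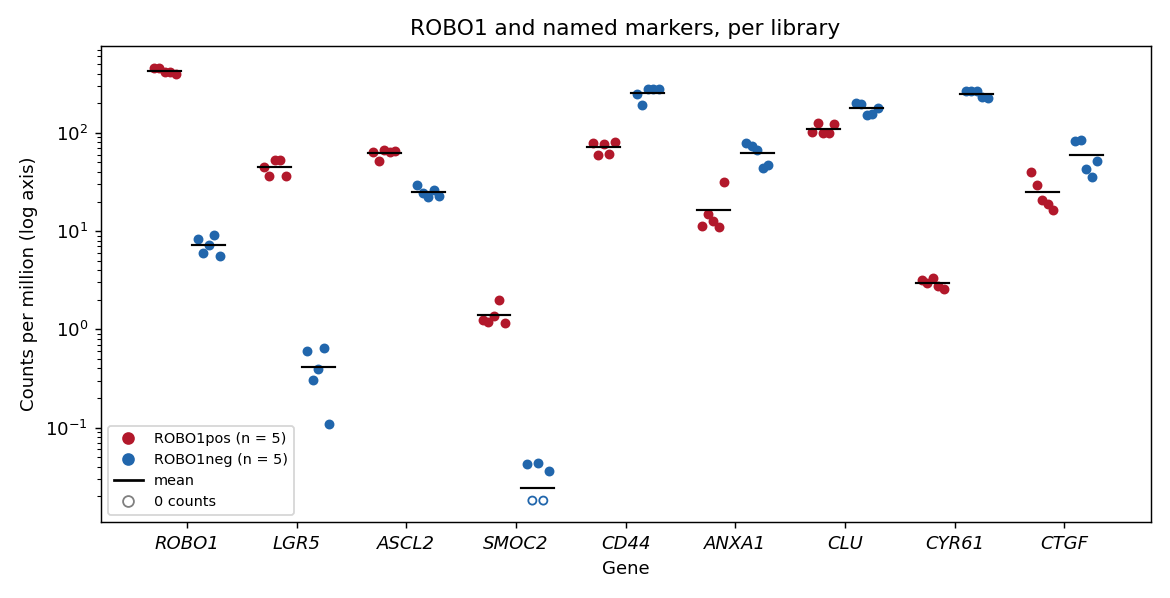
Expression in CPM on a log axis for ROBO1 and the named markers, with 1 point per library, 5 libraries per group and a line at each group mean; open points are libraries with 0 counts. LGR5 was at 44.7 CPM in ROBO1pos and 0.409 CPM in ROBO1neg, and CYR61 at 2.96 and 251 CPM.

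Markers of crypt base columnar cells, the LGR5-positive stem cells of the intestinal crypt, moved in both directions. LGR5 was at 44.7 ± 8.49 CPM in ROBO1pos and 0.409 ± 0.220 in ROBO1neg (log2 fold change 6.75, SE 0.23, edgeR adjusted p = 5.3e-12). ASCL2, a transcription factor of these cells, was higher in ROBO1pos at 62.7 ± 6.35 against 24.9 ± 2.80 CPM. SMOC2 was higher as well, at 1.38 ± 0.343 CPM against 3 counts over all ROBO1neg libraries, a ratio of summed counts of 59.1 (95% exact binomial interval 19.9 to 289). CDK6 and MEX3A were also higher in ROBO1pos, whereas AXIN2, a feedback target of Wnt signalling, was higher in ROBO1neg at 1209 ± 74.6 against 471 ± 17.8 CPM. Of the 22 marker genes tested, 12 were higher in ROBO1pos, 7 were higher in ROBO1neg and 3 did not pass, and as a list they did not pass camera's test against other genes (adjusted p = 0.346). OLFM4 and PROM1 had too few counts to be tested. Wnt and beta-catenin target genes likewise did not pass as a list (camera adjusted p = 0.176), with 18 of 33 higher in ROBO1pos and 8 higher in ROBO1neg, among them CCND1, which encodes cyclin D1, at 405 ± 36.2 CPM against 3580 ± 455 in ROBO1neg. LGR5 lies in a stretch of chromosome 12 whose 55 tested genes had a median log2 fold change of 0.70, and AXIN2 in one of chromosome 17 with a median of -0.47.

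Regenerative or fetal-like epithelial markers were higher in ROBO1neg, with 26 of 37 higher there, 8 higher in ROBO1pos and 3 not passing (camera adjusted p = 0.0034; adjusted p = 0.260 with an estimated correlation). EMP1 was at 148 ± 9.24 CPM in ROBO1neg and 2.69 ± 0.726 in ROBO1pos. ANXA1 and CLU were higher in ROBO1neg by smaller factors, with log2 fold changes of -1.92 (SE 0.27) and -0.70 (SE 0.09). CD44, a hyaluronan receptor that belongs to the crypt base list, was at -1.83 (SE 0.12). SERPINB5, a serpin, went the other way, with a log2 fold change of 2.69 (SE 0.08), and lies on chromosome 18 in a stretch whose tested genes had a median of 1.07. YAP and TAZ target genes, which respond to the Hippo pathway's effectors, were higher in ROBO1neg in 24 of 27 cases and higher in ROBO1pos in 2 (camera adjusted p = 6.0e-06; adjusted p = 0.046 with an estimated correlation). CYR61 was at 251 ± 22.1 CPM in ROBO1neg and 2.96 ± 0.303 in ROBO1pos, and CRIM1 at 219 ± 23.7 against 5.72 ± 0.471. CTGF differed less, with a log2 fold change of -1.24 (SE 0.27).

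Mesenchymal genes and genes of adhesion and matrix turnover were also higher in ROBO1neg. Of 31 mesenchymal and EMT genes, 22 were higher in ROBO1neg and 6 higher in ROBO1pos (camera adjusted p = 0.0011; adjusted p = 0.046 with an estimated correlation). VIM, the intermediate filament vimentin, was at 508 ± 21.8 CPM in ROBO1neg and 9.96 ± 1.16 in ROBO1pos, and the receptor tyrosine kinase AXL at 268 ± 34.8 against 5.30 ± 0.948. SNAI1, a repressor of E-cadherin, was higher in ROBO1pos at 9.32 ± 0.496 against 3.83 ± 0.459 CPM. Proteases and protease inhibitors of the matrix were higher in ROBO1neg in 29 of 36 cases, with 5 higher in ROBO1pos (camera adjusted p = 3.4e-05; adjusted p = 0.046 with an estimated correlation). ADAM19, a metalloprotease, was at 203 ± 12.8 CPM in ROBO1neg against 3.83 ± 0.395, and the inhibitor TIMP2 at 539.6 ± 33.4 against 73.3 ± 3.36. Integrins and adhesion receptors were higher in ROBO1neg in 30 of 40 cases and in ROBO1pos in 8 (camera adjusted p = 5.9e-04; adjusted p = 0.062 with an estimated correlation), with ITGA3 at 622 ± 67.2 against 40.6 ± 3.96 CPM. Collagens, laminins and other matrix genes did not pass as a list (camera adjusted p = 0.096), with 25 of 40 higher in ROBO1neg and 13 higher in ROBO1pos. With the filter of 5 CPM in 5 libraries the list passed camera as higher in ROBO1neg (adjusted p = 0.032). COL4A1, a basement membrane collagen, was higher in ROBO1pos with a log2 fold change of 5.41 (SE 0.13), and COL18A1 was at 462 ± 24.4 CPM in ROBO1neg against 102 ± 11.1. Wnt ligands, receptors and secreted regulators were higher in ROBO1neg in 20 of 31 cases and in ROBO1pos in 7 (camera adjusted p = 0.014; adjusted p = 0.163 with an estimated correlation), with ROR2, FZD7 and ROR1 among the first and the Wnt co-receptor LRP6 among the second.

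Secretory lineage genes, which mark goblet, Paneth and endocrine cells of the gut, were higher in ROBO1pos in 12 of 14 cases and higher in ROBO1neg in 1 (camera adjusted p = 0.0017; adjusted p = 0.163 with an estimated correlation). TFF3, a goblet cell peptide, was at 11.7 ± 1.69 CPM against 0.121 ± 0.0732, and CHGB, a granin of endocrine cells, went the other way with 7.49 ± 1.15 CPM in ROBO1neg and 3.06 ± 1.12 in ROBO1pos. Enterocyte and colonocyte genes did not pass as a list (camera adjusted p = 0.152), with 12 of 20 higher in ROBO1pos and 6 higher in ROBO1neg. VIL1, the brush border protein villin, was at 503 ± 23.3 CPM in ROBO1pos and 27.7 ± 3.14 in ROBO1neg. Epithelial junction and identity genes divided evenly, with 17 of 40 higher in ROBO1pos and 19 higher in ROBO1neg (camera adjusted p = 0.970), and EPCAM was at 680 ± 22.9 against 303 ± 12.8 CPM. Notch pathway genes did not pass (camera adjusted p = 0.202), with 15 of 28 higher in ROBO1pos and 8 higher in ROBO1neg. NOTCH1 and LFNG were higher in ROBO1pos and NOTCH2 was higher in ROBO1neg. SLIT, ROBO and other axon guidance genes also divided, with 25 of 56 higher in ROBO1pos and 24 higher in ROBO1neg (camera adjusted p = 0.975), and their median log2 fold change was -0.072 while their mean was 0.21. NTN1, a netrin guidance cue, was higher in ROBO1neg with a log2 fold change of -4.92 (SE 0.13), as was the plexin PLXND1, at 112 ± 10.7 against 10.5 ± 1.69 CPM.

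Cytokine, interferon and NF-kB genes were higher in ROBO1neg with the preset correlation, but these calls were lost when the correlation was estimated. Cytokines and chemokines were higher in ROBO1neg in 22 of 28 cases and in ROBO1pos in 5 (camera adjusted p = 0.0077; adjusted p = 0.475 with an estimated correlation). LIF, a cytokine of the interleukin 6 family, was at 154 ± 13.1 CPM in ROBO1neg and 2.50 ± 1.18 in ROBO1pos, and CXCL14 at 36.0 ± 3.68 against 0.528 ± 0.151. Interferon-stimulated genes were higher in ROBO1neg in 27 of 37 cases and in ROBO1pos in 3 (camera adjusted p = 3.9e-04; adjusted p = 0.062 with an estimated correlation), with IFITM3 at 168 ± 15.7 against 2.27 ± 0.529 CPM and SAMD9 the other way, at 47.2 ± 4.22 CPM in ROBO1pos against 6.89 ± 1.09. NF-kB target genes were higher in ROBO1neg in 25 of 27 cases and in ROBO1pos in 1 (camera adjusted p = 0.0011; adjusted p = 0.629 with an estimated correlation). The transcription factor IRF1 was higher in ROBO1neg with a log2 fold change of -2.24 (SE 0.13), and SOD2, the mitochondrial superoxide dismutase, was the member higher in ROBO1pos, at 58.5 ± 3.66 against 46.0 ± 3.95 CPM. Antigen presentation genes did not pass (camera adjusted p = 0.060), but lay near the threshold and passed in 6 of the 10 fits without 1 library, with 13 of 24 higher in ROBO1neg and 4 higher in ROBO1pos. They also passed camera with no filter beyond 1 count (adjusted p = 0.018), with the replicate block (0.035) and once the median of each gene's neighbours was removed (0.0045). CD74, the invariant chain of class II molecules, was at 69.7 ± 30.4 CPM in ROBO1neg and 0.541 ± 0.379 in ROBO1pos. MAPK pathway output genes did not pass (camera adjusted p = 0.071), with 18 of 28 higher in ROBO1neg and 7 higher in ROBO1pos, among them ETV1 at 158 ± 8.13 against 48.9 ± 4.15 CPM. As a list they passed camera with no filter beyond 1 count (adjusted p = 0.030), with the replicate block (0.047) and without ROBO1pos replicate 5 (0.0498). Growth factors and angiogenic factors divided, with 19 of 42 higher in ROBO1pos and 17 higher in ROBO1neg (camera adjusted p = 0.738), and their median log2 fold change was 0.0075 while their mean was -0.11 and the test pointed down. INHBB, an inhibin subunit, was higher in ROBO1pos at 251 ± 31.7 against 52.8 ± 5.20 CPM, and PDGFB higher in ROBO1neg at 102 ± 8.58 against 10.4 ± 1.81.

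**Figure D2:**
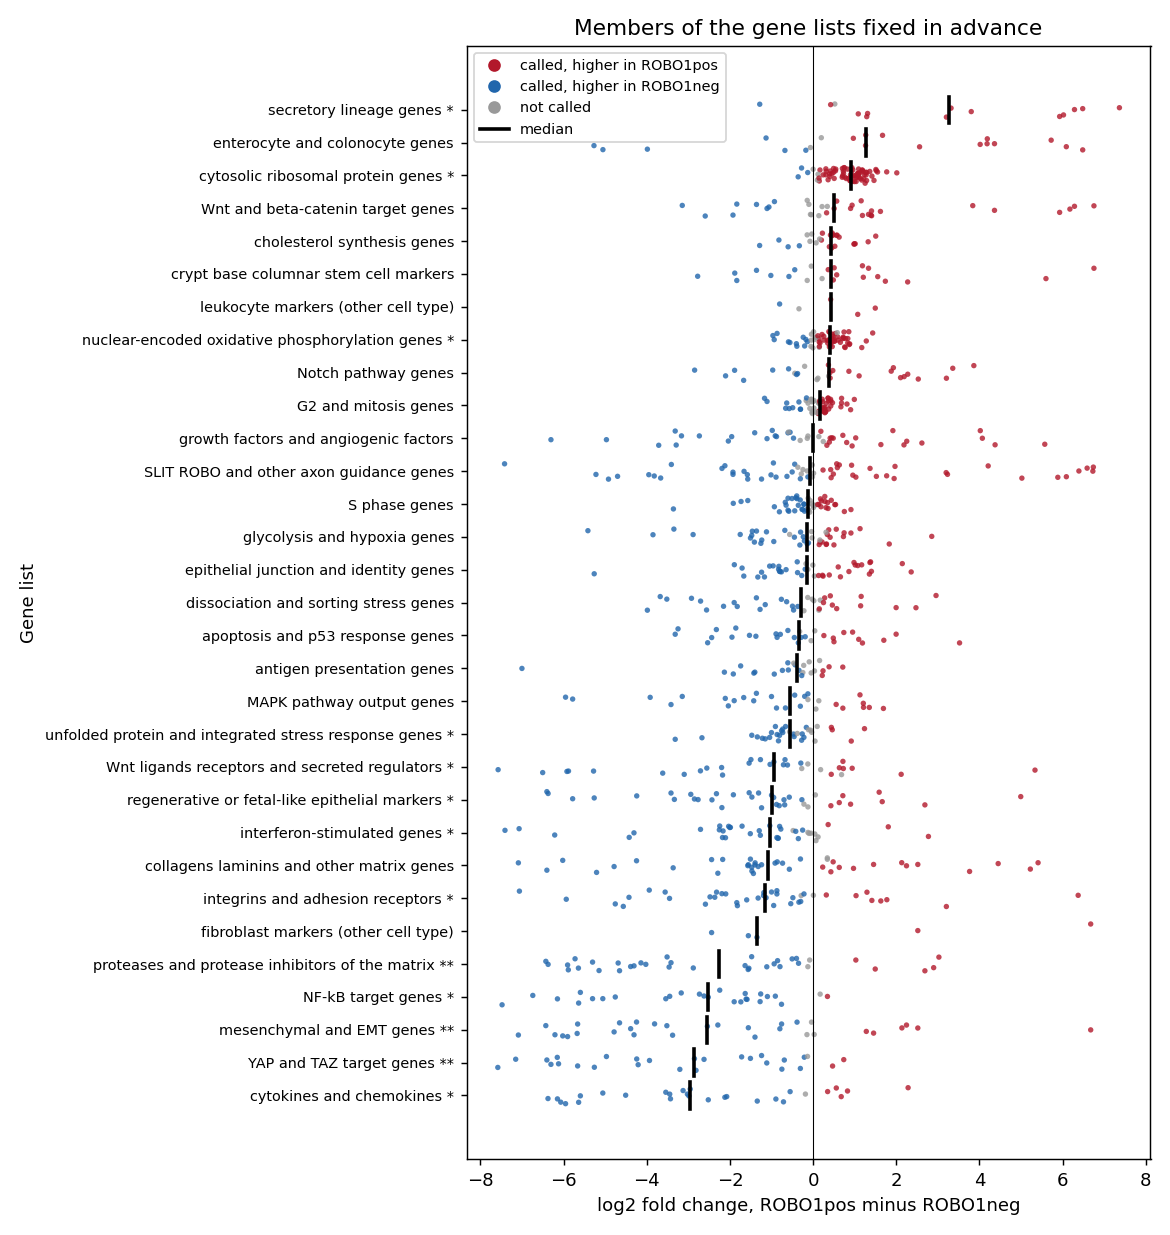
The log2 fold change, ROBO1pos minus ROBO1neg, of each tested member of the 31 gene lists with 5 or more tested genes, with a black bar at the list median; 1 asterisk marks lists that passed camera with the preset correlation and a pair of asterisks those that also passed with an estimated correlation. The list medians ran from -2.97 for cytokines and chemokines to 3.26 for secretory lineage genes.

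Ribosomal protein and respiratory chain genes were higher in ROBO1pos. Of 76 cytosolic ribosomal protein genes tested, 70 were higher in ROBO1pos, 3 were higher in ROBO1neg and 3 did not pass, with a median log2 fold change of 0.91 (camera adjusted p = 4.8e-13; adjusted p = 0.475 with an estimated correlation). RPL4 was at 3047 ± 132 CPM in ROBO1pos and 1041 ± 9.04 in ROBO1neg, and RPL22 at 1001 ± 42.3 against 294 ± 5.59. Their log2 fold changes of 1.55 and 1.77 were 0.75 and 1.01 once the median of their neighbours was removed. RPS15 was higher in ROBO1neg, with a log2 fold change of -0.28 (SE 0.05), but lies at the end of chromosome 19 where 98 tested genes had a median of -1.01, and was at 0.68 once the median of its neighbours was removed. These genes have many processed pseudogenes, so their counts are uncertain where reads could be shared between copies. The share of reads aligned to several places was 24.6% ± 0.875 in ROBO1pos and 21.2% ± 0.398 in ROBO1neg (exact two-sided permutation p = 0.00794). Of 66 nuclear-encoded oxidative phosphorylation genes, 45 were higher in ROBO1pos and 11 were higher in ROBO1neg (camera adjusted p = 9.1e-04; adjusted p = 0.629 with an estimated correlation). ATP5A1 and COX5A were higher in ROBO1pos and lie on chromosomes 18 and 15 in stretches with median log2 fold changes of 1.07 and 0.68, while NDUFB5, higher in ROBO1neg, lies on chromosome 3 in a stretch with a median of -0.86 and went from -0.93 to -0.075, no longer called, once the median of its neighbours was removed. Mitochondrially encoded genes had 0 tested members and were not analysed here.

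RRM2, a subunit of ribonucleotide reductase, was at 313 ± 26.3 CPM in ROBO1neg and 105 ± 9.98 in ROBO1pos, and ECT2, a regulator of cytokinesis, at 251 ± 8.82 against 112 ± 5.62. S phase genes did not pass as a list (camera adjusted p = 0.160), with 24 of 49 higher in ROBO1neg and 15 higher in ROBO1pos, though they passed as higher in ROBO1neg once the median of each gene's neighbours was removed (adjusted p = 0.018). Genes of G2 and mitosis did not pass either (camera adjusted p = 0.181), with 30 of 55 higher in ROBO1pos and 10, ECT2 among them, higher in ROBO1neg. BLM was called higher in ROBO1pos with a log2 fold change of 0.75, and was at -0.10 and no longer called once the median of its neighbours on chromosome 15 was removed. Glycolysis and hypoxia genes divided, with 16 of 43 higher in ROBO1pos and 22 higher in ROBO1neg (camera adjusted p = 0.293), and the hypoxia-inducible factor EPAS1 was at 199 ± 28.2 CPM in ROBO1neg against 4.67 ± 0.552 and PDK3 at 314 ± 49.2 CPM in ROBO1pos against 43.3 ± 4.39. Cholesterol synthesis genes did not pass (camera adjusted p = 0.064), with 17 of 26 higher in ROBO1pos and 4 higher in ROBO1neg. They lay near the threshold and passed camera with no filter beyond 1 count (adjusted p = 0.039) and with the replicate block (0.036). They also passed once the median of each gene's neighbours was removed (0.036) and in 2 of the 10 fits without 1 library. Unfolded protein and integrated stress response genes were higher in ROBO1neg in 22 of 33 cases and in ROBO1pos in 4 (camera adjusted p = 0.0077; adjusted p = 0.629 with an estimated correlation), with the chaperone PDIA4 at 365 ± 5.02 against 157 ± 10.3 CPM. Dissociation and sorting stress genes did not pass (camera adjusted p = 0.261), with 17 of 34 higher in ROBO1neg and 11 higher in ROBO1pos. KLF4 was at 36.8 ± 5.84 CPM in ROBO1neg against 2.33 ± 0.473, and NR4A2 at 15.8 ± 1.81 CPM in ROBO1pos against 2.01 ± 0.401. Apoptosis and p53 response genes did not pass either (camera adjusted p = 0.261), with 17 of 30 higher in ROBO1neg and 10 higher in ROBO1pos. BCL2, an inhibitor of apoptosis, was at 16.4 ± 1.27 CPM in ROBO1pos and 1.41 ± 0.323 in ROBO1neg.

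Markers of other cell types reached at most 27.4 CPM in either population, that of LAPTM5. Of 5 fibroblast markers tested, 2 were higher in ROBO1pos and 3 in ROBO1neg (camera adjusted p = 0.683), and their median log2 fold change was -1.35 while their mean was 0.77 and the test pointed down. COL1A1 was at 4.87 ± 0.702 CPM in ROBO1pos and 14.3 ± 2.65 in ROBO1neg, and COL1A2 was at 1.97 ± 1.53 and 0.353 ± 0.172. Of 5 leukocyte markers, 3 were higher in ROBO1pos and 1 in ROBO1neg (camera adjusted p = 0.481), with LAPTM5 at 27.4 ± 2.02 CPM in ROBO1pos against 13.0 ± 2.21. LYZ, at 2.25 ± 0.374 against 1.69 ± 0.323 CPM, was no longer called when ROBO1pos replicate 4 was left out (log2 fold change 0.31) or when ROBO1neg replicate 3 (0.42), 4 (0.36) or 5 (0.34) was, nor with DESeq2 (0.41, adjusted p = 0.053) or once the median of its neighbours was removed (0.17). The 3 endothelial markers tested, ESAM, VWF and FLT1, were all higher in ROBO1neg but at most 4.47 CPM there, and were too few for a list test. Adjusted over the list alone, the counts of calls were the same for all lists except epithelial junction genes, of which 20 were then higher in ROBO1neg, oxidative phosphorylation genes, of which 47 were then higher in ROBO1pos, and antigen presentation genes, of which 12 were then higher in ROBO1neg. In all, camera with its preset correlation called 3 of the 31 lists higher in ROBO1pos and 10 higher in ROBO1neg, and with an estimated correlation it called 0 and 3. Of 100 splits of the libraries into 5 and 5, 39, the real one included, gave at least 13 list calls with the preset correlation.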

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

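The spread expected from the source genes, in the last paragraph, was computed after the result was seen. No other test in this part was chosen after its own result was seen, but the patterns were noticed in these data first, and the median of the ribosomal protein list and some residual ratios were known when the bounds were set. Among 334 sets of 5 libraries (named genes and library measures), 22 held a library far from the others of its group, where chance gives about 16.7. In ROBO1pos, replicate 5 stood apart for ANXA1 (31.9 CPM), MMP14 (4.97), EPCAM (720), CHGB (1.11), SAMD9 (39.7), LFNG (139) and COX5A (240). Replicate 3 stood apart for ALPK2 (0.426), SMC4 (259) and ZMYND11 (0.542), replicate 4 for SMOC2 (1.98) and LYZ (2.91), replicate 2 for ASCL2 (51.7), and replicate 1 for SNAI1 (10.2) and for the share of reads aligned to several places (26.2%). In ROBO1neg, replicate 5 stood apart for ASAP1 (296) and EPAS1 (250), replicate 1 for LIF (176) and SPANXB1 (0.595), replicate 2 for NRG2 (12.3) and RPS15 (240), and replicate 3 for MDK (145).

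Reads aligned to several places, which no gene count uses, made up 24.6% of reads in ROBO1pos and 21.2% in ROBO1neg. The same libraries had more reads on ribosomal protein genes, which have many near-identical pseudogenes, and reads shared with pseudogenes were weighed as a source of the higher ribosomal protein counts. In the 26 of 76 genes with the fewest named pseudogenes (at most 4 each) the median log2 fold change was 0.90 (95% bootstrap interval 0.50 to 1.09). The bound for a cause other than pseudogenes was 0.5. In the third with the most named pseudogenes (at least 15 each) the median was 0.94, little different. These values argue against pseudogenes as the whole source, though the lower end of the interval lies at the bound. Chromosome stretches that differ between the populations were weighed next: after the median of neighbouring genes was removed the median was 0.81 (0.73 to 0.87), and all 76 genes were above 0, which argues against them. Both bootstrap intervals resample genes and leave out the spread between libraries. A difference in ribosomal protein mRNA between the populations may remain as an explanation, and nothing here measured it apart from these counts.

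Genes nearly absent from 1 population still had a few counts there. The residual level of the 50 lowest genes had a median of 1.23% of the ROBO1pos level in ROBO1neg and 0.880% of the ROBO1neg level in ROBO1pos, and it varied between libraries, with replicate 3 highest in ROBO1pos at 1.09% and replicate 4 highest in ROBO1neg at 1.75%. If cells or reads carried over from the other population were the whole source, these genes would vary together, by 1 factor per library. The library terms took a deviance of 564 in ROBO1pos and 635 in ROBO1neg on 4 degrees of freedom, beyond library depth. These genes thus did vary together between libraries in part, which carry-over predicts but which does not single it out. The model gave each gene its own level, so 1 common share over all genes was not tested. After gene and library terms the residual deviance per degree of freedom was 2.89 in ROBO1pos and 2.19 in ROBO1neg (Pearson chi-square 2.78 and 2.14), past the bound of 2. That bound allowed for counting error alone and was wrong, since the spread of the same genes between libraries of their own population, with counting error, would give a Pearson chi-square of 3.22 and 3.41, so this test cannot argue against carry-over. Transcription of each gene at its own low level was left undecided as well: the 20 lowest ratios of abundant genes spread 4.14-fold in ROBO1neg, between the bounds of 3 and 5, and 2.93-fold in ROBO1pos, under the lower bound, which had to be met in both. A mixture of both sources may apply and was not tested.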

How the results depend on the processing

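The regional median removal was chosen after the data were seen; the other alternatives were planned. The counts of called genes stayed within 1.5 times of the reported ones except in the test against 1.5-fold, with 2938 higher in ROBO1pos and 3298 in ROBO1neg. Called lists moved to 0 and 3 with an estimated correlation and to 9 and 19 with fry, which tests no list against other genes. With 1 library left out, 6087 to 6245 genes were higher in ROBO1pos and 5976 to 6148 in ROBO1neg, the ROBO1 log2 fold change was 5.80 to 5.98, and 3 to 4 and 10 to 12 lists were called. Replicate numbers were not taken to pair the samples, since only 3 of 5 same-number correlations (0.062 to 0.169) exceeded 0.1, though all 5 ROBO1pos and 3 of 5 ROBO1neg libraries correlated best with their own number, a hint from the data and not the design. With the replicate block, 6226 and 6086 genes and 4 and 12 lists were called, newly cholesterol synthesis (adjusted p = 0.0357), antigen presentation (0.0355) and MAPK output genes (0.0469). Of 2744 values of named genes under an alternative, 9 kept their direction but were no longer called, 7 of them for LYZ (1 with the replicate block, adjusted p = 0.055), and 2 reversed, both with the regional median removed: BLM at -0.10, no longer called, and RPS15 at 0.68. With it, 760 of the 10696 genes called both times changed direction, since the setting shifts each gene by its neighbours' median. Of 649 list values under an alternative, 592 kept direction and side of the threshold, 10 were no longer called, all with an estimated correlation, and 34 were newly called, 10 of them for antigen presentation, 6 for cholesterol synthesis and 4 for MAPK output genes. S phase genes were newly called with fry and with the regional median removed. List medians whose test direction reversed without a call in either setting were fibroblast markers with no filter (1.898), axon guidance genes with the stricter filter (-0.012), with fry (-0.072), with the regional median removed (-0.10) and in 5 of 10 fits without 1 library (-0.074 to -0.021; all 10 fits, -0.10 to -0.020), and epithelial junction genes with fry (-0.15), with the regional median removed (-0.059) and in 2 of 10 fits without 1 library (-0.145 to -0.129; all 10 fits, -0.20 to -0.060). Upper quartile scaling moved the median of all genes to 0.08, the furthest of the scalings.

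Of 126 possible splits of the 10 libraries into 5 and 5, 100 were run. For genes, 1 of the 100 splits, the real one, called as many (12250). No other split called any gene by edgeR, the 1 tool run on splits (highest 0 after adjustment, 3736 at an unadjusted p under 0.05). Every other split has libraries of both populations on each side, which widens the spread within sides and makes calls unlikely. The splits therefore cannot exclude chance for the number of genes. For lists, 39 of the 100 splits, the real one included, called at least as many as the real split's 13, and the highest other called 17, so these splits cannot exclude chance for the number of lists that camera calls with its preset correlation. They do not support it either, since each keeps part of the real contrast, and calls are expected there if the lists differ. Of the 21 other splits with 4 libraries of a population on 1 side, 20 called as many, and of the 78 with 3 libraries, 18 did.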

Other observations

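The gene families, and the test on genes of low and high expression, were chosen after the result was seen. Genes were also grouped into 25 families by symbol, some of whose members are in the fixed lists too. The calls named here passed camera with the preset correlation and none passed with an estimated one (adjusted p of 0.208 or more), so they describe these libraries only. The median of neighbouring genes was not removed from family values, so shifts of whole chromosome stretches may be part of them. All 9 pregnancy-specific glycoprotein genes tested were higher in ROBO1neg (camera adjusted p = 0.0053), with PSG1 at 155 CPM there and 2.57 in ROBO1pos, although these genes are near-identical. Keratins, filament proteins of epithelia, were higher in ROBO1neg in 16 of 20 cases and higher in ROBO1pos in 4 (camera adjusted p = 0.0092), with KRT13 at 235 against 1.84 CPM and KRT80 with a log2 fold change of -2.76. Serpins were higher in ROBO1neg in 13 of 15 cases (camera adjusted p = 0.0092), and all 5 metallothioneins were higher there too (camera adjusted p = 0.019), MT2A at 167 against 68.9. Clustered protocadherins were higher in ROBO1pos in 21 of 26 cases and in ROBO1neg in 3 (camera adjusted p = 0.0092), and 7 of 9 aldo-keto reductases were higher in ROBO1pos as well (camera adjusted p = 0.018). So were 6 of 7 MAGE and SPANX genes (camera adjusted p = 0.019), which are normally restricted to the germ line, with MAGEC2 at 16.0 against 0.460 CPM. Of 35 HOX genes, 16 were higher in each population, and as a family they did not pass (camera adjusted p = 0.688). Among those with the smallest adjusted p, HOXB2, HOXB3, HOXB4, HOXB6, HOXB7, HOXB8 and HOXB9 were all higher in ROBO1neg. Their log2 fold changes ran from -5.41 (HOXB2) to -1.89 (HOXB9), with HOXB8 at 276 CPM in ROBO1neg against 25.6.

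Whole stretches of chromosomes differed together. Some of the 34 shifted stretches were short gene-family loci. The 22 genes of chromosome 5 from 140966476 to 141512975 (PCDHAC2 to PCDHGA6) had a median log2 fold change of 1.98. The 25 of chromosome 19 from 42507306 to 43820634, which include pregnancy-specific glycoprotein genes, had one of -3.42. For 31 genes of chromosome 11 from 767222 to 2318204 (median 0.45) the 95% bootstrap interval ran from -0.060 to 1.12. The median log2 fold change was -0.51 over the 862 tested genes of chromosome 17 and -0.53 over the 272 of chromosome 13. It was 1.07 (95% bootstrap interval 0.95 to 1.28) over 122 genes of chromosome 18 from 26016253 to 80247514, 0.68 (0.57 to 0.80) over 267 genes of chromosome 15 from 63277605 to 101976605, -0.86 (-0.91 to -0.75) over 349 genes of chromosome 3 from 119211742 to 198043720 and -1.01 (-1.21 to -0.88) over 98 genes of chromosome 19 from 281043 to 3971099. All these intervals resample genes within stretches whose ends were chosen on the same values. They leave out that choice, the correlation of neighbours and the spread between libraries. On chromosome 10, the neighbours ZMYND11 (130088 to 254637) and DIP2C (274201 to 689668) were at 0.288 and 0.0692 CPM in ROBO1pos against 40.4 and 9.60 in ROBO1neg. LARP4B (806914 to 988341), the first tested gene beyond them, was at 43.4 and 44.2 CPM. This pair was 1 of 20 runs of adjacent genes with 5 CPM or more in 1 population and under 2% of that in the other. Some other runs were members of 1 gene family, such as AKR1C3 with AKR1C4 and PSG8 with PSG1.

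A hypothesis is that, gene-family loci apart, ROBO1pos and ROBO1neg cells are genetically distinct subclones of the line with different copy numbers of these stretches. Chance order of genes does not account for them. Log2 fold changes of genes 20 places apart correlated at 0.106, against at most 0.0275 in 1000 shuffled orders. Genes are not independent replicates in these correlations. For co-regulation of close neighbours a value under 0.02 had been predicted at that distance, a bound below the highest shuffled value. Correlations were 0.281 at 1 place apart and 0.0886 at 50. The gene-family loci above held 22 and 25 genes, so co-regulation can reach 20 places. This correlation therefore cannot set co-regulation aside as a source of the stretches. GC content and transcript length left 96.8% of the shift in place. Stretches chosen on genes of middle expression kept their sign in 25 of 26 sets of genes of low or high expression that took no part in the choice (96.2%), as different copy number predicts for the sign, but the size agreed less well. The shift was at least 50% of that in the choosing genes in 20 of the 26 sets. Among the others were genes of high expression on chromosome X (0.0736 against 0.726), chromosome 18 (0.255 against 0.898) and chromosome 5 (-0.0827 against -0.906). Genes of low expression on a stretch of chromosome 19 (0.154 against 0.560) and of chromosome 1 (0.419 against 0.842) also fell short. Genes of low expression on a stretch of chromosome 5 moved the other way (1.03 against -0.906). That stretch, from 139475533 to 154420984, spans the clustered protocadherin locus with its median of 1.98. The chromosome 18 stretch chosen here, from 662986 to 80140346, was longer than the one above. It also covered genes before 25352166, a part whose 81 genes had a median of 0.12. Genes of low expression on the same longer stretch were at 1.17, so its extent was not shown to explain the lower value of those of high expression. Chromatin states that span megabases could give the same values and were not tested. DNA was not analysed here, so whether copy number differs remains open.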
